A study of Homo sapiens with 20 samples.

How the data were processed

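Total RNA for the 20 libraries was depleted of ribosomal RNA (RiboCop), made into libraries with the KAPA RNA HyperPrep kit and sequenced in pairs on a NovaSeq, per the labels' protocols. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with HISAT2 2.2.1 to GRCh38 (hg38) and counted per gene with featureCounts of Subread 2.0.5. The authors deposited whole-number counts per gene symbol, 1 table per library and 1 table for the series. The strand, pairing and multiple-mapping settings behind them are not given in the sources used here. Even counts are preferred in every library (a count of 1 occurred in 1011 genes and a count of 2 in 2371 genes, means over the 20 libraries), so both reads of a pair may have been counted, and a count then stands for less than 1 molecule. The authors also deposited a table of normalized signal values named as CPM, whose ratio to the counts is 1 constant per library. It was used only in an alternative. The length column deposited with the counts, an exon length per gene of another unit, was not used.

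The tables per library hold 59235 gene names, of which 59196 are shared with the series-wide table, with 0 differences in count. In the tables per library, 16 genes with long exon lists are broken over 61 lines without a usable count; they were read from the series-wide table in an alternative only. The 39 ribosomal RNA names, absent from the series-wide table, took at most 0.00152% of the counts of a library and stayed out of library sizes. No 2 libraries of a group were duplicates: the lowest median chi-square per gene of a pair was 2.33, against 0.455 for sampling noise. Reads of antisense, overlapping and near-identical genes cannot be told apart without the counting settings, so such genes are uncertain.

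Groups and replicate numbers came from the sample titles. The counts of the 20 libraries entered 1 fit with a mean per group in edgeR 4.0.16 (R 4.3.3), after its filter on low counts (filterByExpr) and scaling by the trimmed mean of M-values (TMM). Each of the 4 comparisons had a quasi-likelihood test with Benjamini-Hochberg adjustment over the 21035 genes tested. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.203. Log2 levels carry a prior count of 2. Where a group had 0 counts, the fold was bounded by a floor of 3 counts over the group, and where it had 1 to 3 counts a ratio with its 95% counting interval is given. A count of 0 in a library allows up to 0.0723 CPM in F1, the shallowest, and 0.0141 CPM in F4.

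Genes were named by a rule. It took 10 fixed genes (among them ACTA2, COL1A1, COL1A2, MMP1, TIMP1, IDO1, IL6, CDKN1A and MKI67). It added the 6 highest and 6 lowest log2 fold changes among called genes with at least 5 CPM in the higher group and no overlap between the groups. Unnamed, non-coding and pseudogene symbols and those linked to sex were left out. It then took up to 3 called members of each list described, by size of change, or up to 2 by p where no member was called. A gene named in 1 comparison could be given in the others, and some genes the rule chose are not described here. The 31 gene lists were written from general knowledge. Those on the cytoskeleton, matrix and immune response were contractile and smooth muscle cytoskeleton, TGF-β target genes, fibrillar collagens and matrix glycoproteins, basement membrane, collagen processing and cross-linking, matrix-degrading proteases, protease inhibitors of the matrix, interferon-γ response, type I interferon stimulated genes, MHC class I and immunoproteasome, MHC class II, and NF-κB and TNF response. Those on growth and stress were cell cycle, p53 targets and cell cycle inhibitors, pro-apoptotic and death receptor, anti-apoptotic, unfolded protein response, amino acid starvation and ATF4 targets, hypoxia and glycolysis, cholesterol and sterol synthesis, nuclear genes of the mitochondrial respiratory chain and NRF2 and oxidative stress. The others were WNT, IGF and growth factor signalling, quiescent fibroblast and adipogenic factors, immediate early genes and heat shock, ribosomal proteins, mitochondrial genome, and markers of adipocytes, endothelial cells, leukocytes and epithelial cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The groups, tests, lists, naming rule and the 15 other settings below were fixed before the data were examined.

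These other settings were DESeq2-type and upper-quartile scaling, no filter and a stricter one (mean of at least 5 CPM), the replicate number as a block, only the libraries compared in the fit, and the series-wide count table. The others were DESeq2 1.42.0, limma-voom, limma-trend on the deposited normalized values, the estimated correlation, fry, split myofibroblast controls, a 2-fold limit and leaving out each of the 20 libraries in turn. Another 5 were added after seeing the data: halved counts, the first component of the deviations from group means as a covariate (residual component), libraries numbered 1, 2 and 5 only, those numbered 3 and 4 only, and removal of each library's trend with GC content (20 bins; GC of the annotated exons known for 17740 genes, 84.3% of those tested). Genes moved back were counted against independent lists and with split controls. Covariances of fold changes were set against 20 simulations without change and 20 in which only F differed, with genes drawn independently. Replicate numbers were permuted within groups 100000 times against the first component of the deviations from group means. Group labels were regrouped in 100 of the 126 possible splits of 10 libraries.

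The scripts were tested on simulated data with 200 changed genes, drawn independently at the real means and library sizes. Of true log2 changes of 1, edgeR recovered 90.4% for M against F, 95.1% for R against M, 93.5% for P against M and 94.9% for P against R; of changes of 0.5 it recovered 31.1%, 42.4%, 39.3% and 47.5%. It made 6, 7, 7 and 7 false calls among 20416, 20479, 20439 and 20427 simulated genes, where DESeq2 made 32, 31, 24 and 37 among 21035. Camera called 0 of 29 unchanged lists each time and fry 0, 3, 0 and 1, with no correlated lists tested. With resting medium 99 of 100 genes set to return were found. Coordinates come from the RefSeq annotation of GRCh38. TERT had 0 counts in the 20 libraries; the immortalising transgene, strand-specific signal, splicing and variants were not analysed here.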

Results

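The transcriptome of HCA2 cells, a human fibroblast line immortalised with telomerase (hTERT), was measured by RNA sequencing in 20 libraries after 144 h of culture. They form 4 groups of 5 libraries each. Untreated fibroblasts (F) were kept in serum-free medium throughout. Myofibroblasts (M) were made with transforming growth factor β (TGF-β, 5 ng/mL) for 72 h and then kept in serum-free medium. The resting-medium group (R) received TGF-β and then, for 72 h, medium conditioned by unstimulated human mesenchymal stromal cells from adipose tissue. The primed-medium group (P) received TGF-β and then medium from the same kind of stromal cell stimulated beforehand with the cytokines interferon-γ and tumour necrosis factor α. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

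Total counts per library, to 6 significant digits, ran from 41502600 in F1 to 213500000 in F4. They ran from 75610000 to 197967000 in M, from 48023200 to 140491000 in R and from 60872100 to 204619000 in P. Of the genes counted, 21035 passed the filter on low counts and were tested. The first principal component of their log2 levels held 53.8% of the variance and the second 8.07%. FN1, which encodes the matrix glycoprotein fibronectin, took 2.04% ± 0.101 of all counts in F (SD, n = 5) and 8.04% ± 0.649 in M, and the 10 most abundant genes together took 11.7% ± 0.477 and 24.3% ± 0.967. They took 24.0% ± 0.913 in R and 24.2% ± 2.90 in P. Levels are given as CPM on library sizes scaled by the trimmed mean of M-values (TMM), as mean ± SD with n = 5, and changes as log2 fold change ± SE. Intervals and floors cover counting error only; if both reads of a pair were counted, the bounds from floors are too high and the intervals too narrow.

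The first comparison, myofibroblasts against untreated fibroblasts, asked what TGF-β did to these cells. ACTA2, which encodes α-smooth muscle actin, the standard marker of myofibroblasts, stood at 76.8 ± 7.25 CPM in the fibroblasts and at 899.6 ± 155 CPM in the myofibroblasts, a log2 fold change of 3.55 ± 0.25 (adjusted p = 6.11e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The type I collagen chains also rose, COL1A1 by 2.27 ± 0.21 (adjusted p = 4.92e-09) from 13845 ± 1610.3 to 66966 ± 7157 CPM and COL1A2 by 0.86 ± 0.17 (adjusted p = 0.000243). IL6, an inflammatory cytokine, rose by 1.83 ± 0.34 (adjusted p = 0.000131), while MKI67, the proliferation antigen Ki-67, fell by 2.68 ± 0.43 (adjusted p = 2.11e-05). In each of these 5 genes the 5 libraries of one group lay apart from the 5 of the other. The collagenase MMP1 (−0.78 ± 0.34, adjusted p = 0.0695), its inhibitor TIMP1 (0.24 ± 0.21, adjusted p = 0.377), the tryptophan-degrading enzyme IDO1 (−1.14 ± 1.24, adjusted p = 0.492; −3.66 without M5) and the cell cycle inhibitor CDKN1A (0.15 ± 0.080, adjusted p = 0.128) did not pass the test. In the RefSeq annotation of GRCh38, ACTA2 lies on chromosome 10, 88935074 to 88991337, COL1A1 on chromosome 17, 50184101 to 50201631 and COL1A2 on chromosome 7, 94394895 to 94431227.

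**Figure D1:**
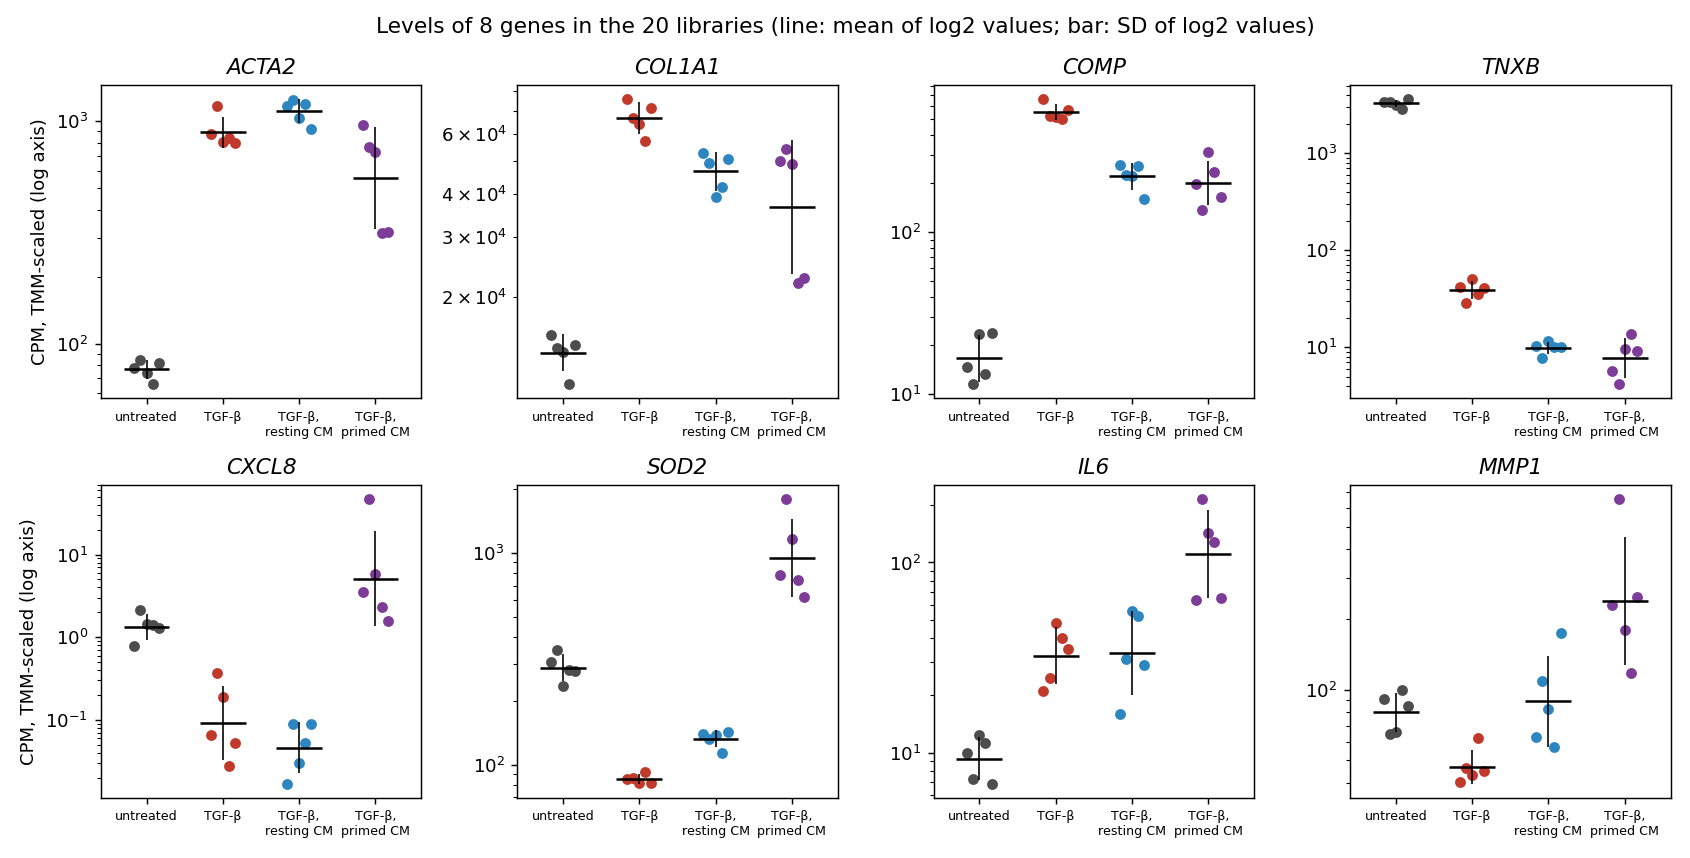
Levels of 8 genes in the 20 libraries, in CPM on TMM-scaled library sizes (log axis), by group, where points are libraries, the line is the mean of the log2 values and the bar their SD (n = 5). ACTA2 averaged 76.8 CPM in F against 899.6 CPM in M, and SOD2 85.7 CPM in M against 1021 CPM in P.

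In all, 9358 genes differed between myofibroblasts and fibroblasts, 4601 higher and 4757 lower (4031 and 5284 with upper-quartile scaling), and 7152 of them had no overlap between the libraries of the groups, where chance gives 0.794% of genes. Of the 9358, 1815 rose and 2424 fell by at least 2-fold. Among the largest rises of genes with at least 5 CPM in M and separated groups were the cartilage genes COL10A1, a collagen of hypertrophic cartilage (9.93 ± 0.43; 0.3004 ± 0.162 CPM in F, 286 ± 40.4 in M), and HAPLN1, which links hyaluronan to proteoglycans (9.90 ± 0.33). They were followed by the cytoskeletal adaptor SORBS2 (7.93 ± 0.24) and LDLRAD4, an inhibitor of TGF-β signalling (7.82 ± 0.20). ST6GAL2, a sialyltransferase, had 3223 counts in the M libraries and 1 in the F libraries, a ratio of 3727 after scaling to the totals (95% counting interval 668.5 to 147258), and KANK4 4011 against 2 (ratio 2319, interval 641.6 to 19157). Within the same limits for F, the largest falls of protein-coding genes were in the alcohol dehydrogenase ADH1B (−14.00 ± 0.30), from 351 ± 20.1 to 0.0206 ± 0.0164 CPM, and in the sialyltransferase ST8SIA1 (−10.60 ± 0.46, or −11.46 without M5), the plasminogen-binding protein CLEC3B (−10.09 ± 0.24), the amino acid transporter family member SLC7A14 (−9.56 ± 0.38), the tight junction protein CLDN11 (−8.10 ± 0.45) and SEC14L5 (−7.79 ± 0.59). The highest adjusted p of these 12 genes was 2.40e-10 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

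Gene lists fixed beforehand were tested with camera at a preset correlation. They can share members and need not be separate responses. Of the 29 with enough members, 16 differed, 7 upward and 9 downward. With a correlation estimated from data, only TGF-β targets and adipocyte markers did. Of the 25 tested TGF-β target genes, 21 rose, 0 fell and 4 did not pass. Adjusted over the list alone, 22 rose and 0 fell (camera adjusted p = 1.64e-17, adjusted p = 0.00199 with an estimated correlation). KANK4 aside, the WNT-pathway regulator DACT1 rose by 5.53 ± 0.12 and the tetraspanin TSPAN2 by 5.27 ± 0.30. Among the contractile and smooth muscle genes, 18 of 23 rose, 1 fell and 4 did not pass. These counts were 18 and 2 adjusted over the list alone (camera adjusted p = 1.94e-12, adjusted p = 0.0793 with an estimated correlation). Without F4, 2 of them fell. TAGLN, an actin-binding protein of smooth muscle, rose by 4.55 ± 0.27, the collagen receptor subunit ITGA11 by 4.51 ± 0.12 and calponin, CNN1, by 3.65 ± 0.19. Of the 33 tested fibrillar collagens and matrix glycoproteins, 23 rose, 7 fell and 3 did not pass. By camera, adjusted p = 2.86e-07 (adjusted p = 0.254 with an estimated correlation), and 25 rose and 7 fell adjusted over the list alone. COL10A1 was followed by the fibril collagen COL11A1 (7.59 ± 0.21) and periostin, POSTN (3.80 ± 0.22).

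Other matrix lists went both ways and their tests did not pass. Among the basement membrane genes, 3 of 14 rose, 7 fell and 4 did not pass. Camera gave adjusted p = 0.591, and 3 rose and 7 fell adjusted over the list alone. The type IV collagen chains COL4A1 (4.73 ± 0.18) and COL4A2 (3.62 ± 0.14) and the laminin chain LAMA4 (−1.69 ± 0.12) changed most. Of the 23 tested collagen processing and cross-linking genes, 11 rose, 7 fell and 5 did not pass. As a list they had camera adjusted p = 0.145, with 11 up and 7 down adjusted over the list alone. The transglutaminase TGM2 rose by 3.51 ± 0.27, the prolyl hydroxylase subunit P4HA3 by 3.27 ± 0.13 and the lysyl oxidase LOXL3 by 2.39 ± 0.10. Among the matrix-degrading proteases, 14 of 27 rose, 9 fell and 4 did not pass. The list as a whole gave camera adjusted p = 0.504, and the counts adjusted over the list alone were 14 and 10. Stromelysin-2, MMP10, rose by 3.84 ± 0.45, while the urokinase gene PLAU fell by 3.50 ± 0.20 and ADAMTS15 by 3.43 ± 0.41. Of the 13 tested protease inhibitors of the matrix, 3 rose, 7 fell and 3 did not pass. It came to 3 and 7 adjusted over the list alone, with camera adjusted p = 0.123. The plasminogen activator inhibitor SERPINB2 fell by 5.65 ± 0.36 and the metalloproteinase inhibitor TIMP4 by 3.98 ± 0.59.

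Among the NF-κB and TNF response genes, 3 of 37 rose, 27 fell and 7 did not pass. The numbers adjusted over the list alone were 3 and 27 (camera adjusted p = 7.16e-08, adjusted p = 0.171 with an estimated correlation). The complement component C3 fell by 5.93 ± 0.62, from 155 ± 36.3 to 2.52 ± 1.52 CPM, and the pentraxin PTX3 fell by 5.60 ± 0.31. The eotaxin gene CCL11, with 87 counts in F and 0 in M, was at least 25.1-fold lower against a floor of 3 counts over the group, if counts stand for single molecules. Of the 34 tested type I interferon stimulated genes, 2 rose, 24 fell and 8 did not pass. Over the list alone, the adjusted calls were 2 up and 24 down (camera adjusted p = 1.47e-06, adjusted p = 0.141 with an estimated correlation). The antiviral genes OAS1 (−6.71 ± 0.84), RSAD2 (−4.75 ± 0.93) and OAS3 (−4.24 ± 0.48) fell most; without M5 they stood at −9.50, −5.56 and −4.95. Among the interferon-γ response genes, 7 of 29 rose, 14 fell and 8 did not pass. Adjustment over the list alone gave 7 higher and 15 lower (camera adjusted p = 0.0290, adjusted p = 0.254 with an estimated correlation). Complement factor B, CFB, fell by 4.66 ± 0.33, and the apolipoprotein L genes APOL3 and APOL1 fell by 4.00 ± 0.21 and 3.09 ± 0.15. Of the 18 tested MHC class I and immunoproteasome genes, 0 rose, 17 fell and 1 did not pass. This list had camera adjusted p = 1.85e-08 (adjusted p = 0.0877 with an estimated correlation), with 0 and 18 adjusted over it alone. They included the immunoproteasome subunit PSMB9 (−3.12 ± 0.24), the peptide-trimming enzyme ERAP2 (−1.90 ± 0.25) and HLA-B (−1.55 ± 0.12). Among the MHC class II genes, 0 of 4 rose, 4 fell and 0 did not pass. With adjustment over these alone, 0 rose and 4 fell. The class II transactivator CIITA changed by −2.68 ± 0.47, HLA-DPA1 by −2.34 ± 0.28 and HLA-DPB1 by −1.49 ± 0.21, and this list was too short for camera. MHC genes have near-identical copies between which counting can split reads.

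Of the 43 tested cell cycle genes, 0 rose, 37 fell and 6 did not pass. Tested with camera, the list had adjusted p = 7.90e-09 (adjusted p = 0.356 with an estimated correlation), and 0 and 38 passed adjusted over the list alone. The ribonucleotide reductase subunit RRM2 fell by 2.95 ± 0.41, the mitotic kinesin KIF20A by 2.71 ± 0.47 and MKI67 as given. Among the p53 targets and cell cycle inhibitors, 9 of 24 rose, 5 fell and 10 did not pass. Adjusted over the list alone, 9 rose and 6 fell (camera adjusted p = 0.0662). This list passed without F2 or M2 (camera adjusted p 0.0471 to 0.0480). The quinone oxidoreductase TP53I3 rose by 3.05 ± 0.22, the cyclin-dependent kinase inhibitor CDKN2B by 2.61 ± 0.11 and the stress gene GADD45B by 2.56 ± 0.13. Of the 32 tested pro-apoptotic and death receptor genes, 8 rose, 9 fell and 15 did not pass. These counts were 9 and 10 adjusted over the list alone (camera adjusted p = 0.674). The death ligand TNFSF10 fell by 6.43 ± 0.73 (8.85 without M2) and the inflammatory caspase CASP1 by 2.02 ± 0.23, while BMF rose by 2.19 ± 0.15. Among the anti-apoptotic genes, 3 of 14 rose, 5 fell and 6 did not pass. By camera, adjusted p = 0.427, and 4 rose and 6 fell adjusted over the list alone. Osteoprotegerin, TNFRSF11B, fell by 2.998 ± 0.15, BIRC3 by 2.47 ± 0.25 and survivin, BIRC5, by 2.33 ± 0.50. Of the 42 tested WNT, IGF and growth factor genes, 22 rose, 17 fell and 3 did not pass. Camera gave adjusted p = 0.309, and 22 rose and 17 fell adjusted over the list alone. The insulin-like growth factors IGF1 and IGF2 rose by 7.56 ± 0.63 and 5.56 ± 0.43, and the activin subunit INHBA by 4.71 ± 0.15.

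Among the amino acid starvation and ATF4 targets, 24 of 26 rose, 0 fell and 2 did not pass. As a list they had camera adjusted p = 2.82e-15 (adjusted p = 0.119 with an estimated correlation), with 25 up and 0 down adjusted over the list alone. The amino acid transporter SLC7A5 rose by 4.49 ± 0.15, the glutathione-degrading enzyme CHAC1 by 3.67 ± 0.17 and the serine synthesis enzyme PSAT1 by 3.29 ± 0.20. Of the 22 tested unfolded protein response genes, 12 rose, 0 fell and 10 did not pass. The list as a whole gave camera adjusted p = 0.00176 (adjusted p = 0.319 with an estimated correlation), and the counts adjusted over the list alone were 12 and 0. HERPUD1 (1.56 ± 0.11), CREB3L2 (1.38 ± 0.075) and XBP1 (1.20 ± 0.067) led. Among the cholesterol and sterol synthesis genes, 0 of 24 rose, 17 fell and 7 did not pass. It came to 0 and 17 adjusted over the list alone, with camera adjusted p = 0.000906 (adjusted p = 0.525 with an estimated correlation). The synthesis enzymes LSS and TM7SF2 fell by 1.54 ± 0.24 and 1.46 ± 0.27. Of the 24 tested NRF2 and oxidative stress genes, 13 rose, 4 fell and 7 did not pass. The numbers adjusted over the list alone were 14 and 4 (camera adjusted p = 0.0378, adjusted p = 0.525 with an estimated correlation). The list did not pass without F4 or M2 (camera adjusted p 0.0506 to 0.0661). The metallothionein genes MT1F and MT1G, near-identical to their neighbours and so uncertain, had 0 counts in F and were at least 22.4-fold and 10.4-fold higher in M. MT2A rose by 2.91 ± 0.27. Among the hypoxia and glycolysis genes, 10 of 33 rose, 11 fell and 12 did not pass. Over the list alone, the adjusted calls were 11 up and 12 down (camera adjusted p = 0.568). The peptide hormone gene ADM fell by 2.64 ± 0.18, while the oxygen sensor EGLN3 rose by 2.04 ± 0.38 and the phosphofructokinase PFKP by 2.02 ± 0.11. Of the 30 tested nuclear genes of the respiratory chain, 7 rose, 2 fell and 21 did not pass. Adjustment over the list alone gave 6 higher and 2 lower (camera adjusted p = 0.211). NDUFA4 and the complex I subunit NDUFA1 rose by 0.55 ± 0.14 and 0.42 ± 0.11. Among the ribosomal protein genes, which have many near-identical pseudogenes, 18 of 42 rose, 0 fell and 24 did not pass. This list had camera adjusted p = 0.00136 (adjusted p = 0.525 with an estimated correlation), with 18 and 0 adjusted over it alone. RPSA rose by 0.57 ± 0.081, RPS2 by 0.42 ± 0.077 and RPS12 by 0.41 ± 0.090, and 10 members rose with upper-quartile scaling, as did 4 of the respiratory chain genes. If 1 library was left out, of the respiratory chain genes 4 rose without M2 and 1 fell without F2 or M3. On omission of 1 library, of the ribosomal genes 11 to 28 rose without M2 or M3.

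Of the 25 tested quiescent fibroblast and adipogenic factors, 6 rose, 16 fell and 3 did not pass. Tested with camera, the list had adjusted p = 0.00494 (adjusted p = 0.0793 with an estimated correlation), and 7 and 16 passed adjusted over the list alone. The ferritin receptor SCARA5, with 1414 counts in F and 0 in M, was at least 408-fold lower. CD34 fell by 5.77 ± 0.32, and PI16, a marker of adventitial fibroblasts, rose by 6.80 ± 0.39. Among the immediate early and heat shock genes, 4 of 28 rose, 13 fell and 11 did not pass. Adjusted over the list alone, 4 rose and 13 fell (camera adjusted p = 0.0378, adjusted p = 0.525 with an estimated correlation). The early growth response gene EGR2 (3.34 ± 0.28) and IER3 (2.16 ± 0.16) rose while EGR3 (−2.31 ± 0.30) fell. Markers of other cell types were measured the same way. Of the 9 tested adipocyte markers, 0 rose, 7 fell and 2 did not pass. These counts were 0 and 7 adjusted over the list alone (camera adjusted p = 0.000853, adjusted p = 0.0367 with an estimated correlation). The aquaglyceroporin AQP7, with 226 counts in F and 0 in M, was at least 65.1-fold lower. The fatty acid receptor CD36 fell by 6.39 ± 0.30 and the lipid droplet gene PLIN4 by 2.30 ± 0.22. Among the endothelial markers, 3 of 11 rose, 4 fell and 4 did not pass. By camera, adjusted p = 0.670, and 3 rose and 4 fell adjusted over the list alone. Of the 8 tested leukocyte markers, 2 rose, 3 fell and 3 did not pass. Camera gave adjusted p = 0.670, and 3 rose and 3 fell adjusted over the list alone. Among the epithelial markers, 5 of 11 rose, 4 fell and 2 did not pass. As a list they had camera adjusted p = 0.901, with 5 up and 4 down adjusted over the list alone. The protein-coding genes of the mitochondrial genome, 13 in number, had 0 counts in the 20 libraries and could not be tested.

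**Figure D2:**
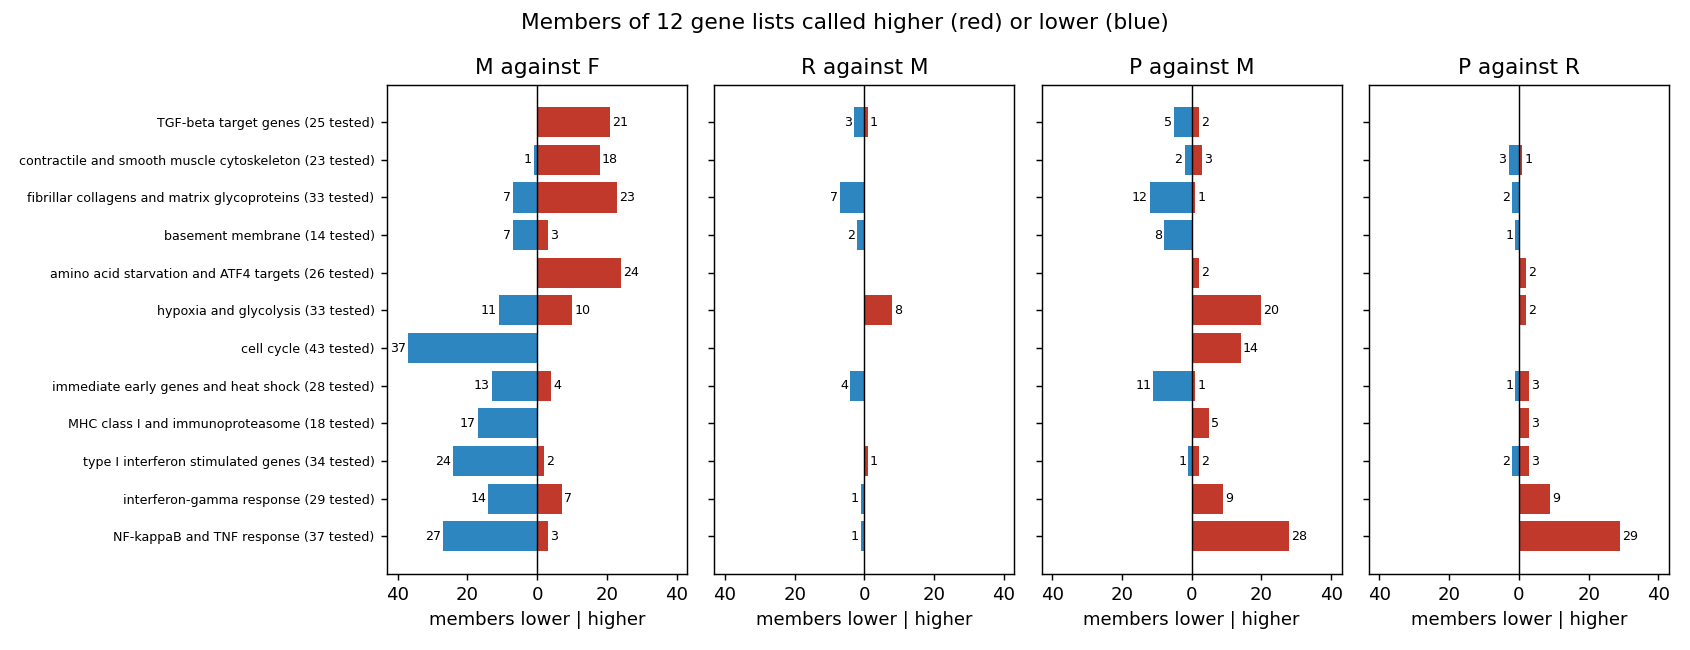
Number of members of 12 gene lists that were higher (red) or lower (blue) in each of the 4 comparisons (edgeR, adjusted p under 0.05). In the NF-κB and TNF response list 27 members were lower in M than in F and 28 were higher in P than in M.

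The second comparison, resting stromal medium against serum-free medium after TGF-β, asked whether unstimulated stromal cells release factors that alter myofibroblasts. TNXB, a tenascin of loose connective tissue, fell by 1.99 ± 0.22 (adjusted p = 2.58e-05), from 39.5 ± 8.12 CPM in M to 9.94 ± 1.38 in R, and the cartilage matrix protein COMP fell by 1.30 ± 0.21 (adjusted p = 0.00145; 554 ± 67.3 to 225 ± 40.2 CPM). Osteoprotegerin, TNFRSF11B, a decoy receptor for TNF-family ligands, rose by 1.33 ± 0.14 (adjusted p = 1.06e-05; 32.2 ± 4.10 to 80.9 ± 6.90 CPM). ACTA2 (0.31 ± 0.23, adjusted p = 0.565), COL1A1 (−0.51 ± 0.20, adjusted p = 0.201) and COL1A2 (−0.23 ± 0.17, adjusted p = 0.570) did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Nor did MMP1 (1.03 ± 0.34, adjusted p = 0.126), IDO1 (0.71 ± 1.25; 3.22 without M5 and −0.98 without R1), IL6 (0.12 ± 0.33), CDKN1A (0.20 ± 0.080) or MKI67 (0.90 ± 0.42), whose adjusted p lay between 0.214 and 0.913 from IDO1 on. TIMP1 rose by 0.87 ± 0.21 (adjusted p = 0.0293), a call lost without M1, M3, M5, R2, R3 or R5 (adjusted p 0.0622 to 0.1005).

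In all, 453 genes differed between R and M, 183 higher and 270 lower (159 and 325 with upper-quartile scaling, 649 and 620 with the replicate block, 857 and 747 with the residual component), and 383 of them had no overlap between the groups. This count came to 232 without M1, 233 without M3, 222 without M5, 222 without R2, 229 without R3, 257 without R4 and 279 without R5. The 2-fold changes numbered 42 up and 58 down. Among genes with at least 5 CPM in the higher group and separated groups, the largest rises were in the interleukin-7 receptor IL7R (1.64 ± 0.37), the methyltransferase INMT (1.58 ± 0.36), the adenylate kinase AK4 (1.47 ± 0.23, adjusted p = 0.000932), the calcium-binding protein S100A4 (1.44 ± 0.33), the aldolase ALDOC (1.39 ± 0.36) and TNFRSF11B. The IL7R call was lost without M1, M3, M5, R2, R3 or R4 (adjusted p 0.0515 to 0.0760). That of INMT was lost without M1, M3, M5 or R2 (adjusted p 0.0504 to 0.0650). S100A4 was lost without M1, M3, M5, R2 or R3 (adjusted p 0.0511 to 0.0840), and ALDOC without any 1 of the 10 libraries (adjusted p 0.0576 to 0.140). Within the same limits the largest falls, after TNXB, were in the collagen COL15A1 (−1.56 ± 0.36), the matrix Gla protein MGP (−1.49 ± 0.37), PTX3 (−1.31 ± 0.26, adjusted p = 0.00859), COMP and the potassium channel KCNK15 (−1.29 ± 0.17, adjusted p = 0.000207), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. COL15A1 was lost without M1, M3, M5, R2 or R5 (adjusted p 0.0547 to 0.0808). MGP was lost without M1, M3, M4, M5, R1, R2, R3 or R5 (adjusted p 0.0509 to 0.106).

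Of the gene lists, 12 of 29 differed, 5 upward and 7 downward, and 0 did with an estimated correlation (limma's camera; 3 at an unadjusted p under 0.05). Of the 33 tested hypoxia and glycolysis genes, 8 rose, 0 fell and 25 did not pass. The list as a whole gave camera adjusted p = 1.49e-13 (adjusted p = 0.246 with an estimated correlation), and the counts adjusted over the list alone were 19 and 0. Besides ALDOC, lost without any 1 of the 10 libraries (adjusted p 0.0576 to 0.140), the mitophagy receptor BNIP3 rose by 1.01 ± 0.17 and the pyruvate dehydrogenase kinase PDK1 by 0.90 ± 0.18. Among the fibrillar collagens and matrix glycoproteins, 0 of 33 rose, 7 fell and 26 did not pass. It came to 0 and 7 adjusted over the list alone, with camera adjusted p = 0.00137 (adjusted p = 0.637 with an estimated correlation). COL5A3 fell by 1.27 ± 0.13, the microfibril protein MFAP4 by 0.66 ± 0.13 and COL5A1 by 0.60 ± 0.14. The COL5A1 call was lost without M1, M3, M5, R2, R3, R4 or R5 (adjusted p 0.0547 to 0.0893). Of the 14 tested basement membrane genes, 0 rose, 2 fell and 12 did not pass. The numbers adjusted over the list alone were 1 and 5 (camera adjusted p = 0.000240, adjusted p = 0.246 with an estimated correlation). Besides COL15A1, nidogen, NID1, fell by 0.42 ± 0.094, lost without M1, R2 or R5 (adjusted p 0.0534 to 0.0581). Among the TGF-β target genes, 1 of 25 rose, 3 fell and 21 did not pass. Over the list alone, the adjusted calls were 1 up and 4 down (camera adjusted p = 0.0422, adjusted p = 0.563 with an estimated correlation). This list did not pass without M1, M2, M5, R1, R3 or R4 (camera adjusted p 0.0723 to 0.199), and 0 rose with upper-quartile scaling. Besides COMP, the AP-1 subunit JUNB fell by 0.70 ± 0.14. After removal of 1 library, of the basement membrane genes 0 to 1 fell without M1, M3, M5, R2 or R5. Once 1 library was removed, of the fibrillar matrix genes 3 to 4 fell without M1, M3, M5, R2, R3, R4 or R5. Leaving out 1 library, of the hypoxia genes 4 to 5 rose without M1, M3, M5, R2, R3 or R5. When 1 library was omitted, of the TGF-β target genes 0 rose without M1, M3, M4, M5, R2, R3, R4 or R5.

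Of the 28 tested immediate early and heat shock genes, 0 rose, 4 fell and 24 did not pass. Adjustment over the list alone gave 0 higher and 11 lower (camera adjusted p = 0.000240, adjusted p = 0.375 with an estimated correlation). EGR3 fell by 1.53 ± 0.30 and the AP-1 subunit JUN by 0.81 ± 0.15. Among the quiescent fibroblast and adipogenic factors, 1 of 25 rose, 5 fell and 19 did not pass. This list had camera adjusted p = 0.0276 (adjusted p = 0.276 with an estimated correlation), with 2 and 7 adjusted over it alone. This list did not pass without M4, R1 or R2 (camera adjusted p 0.0560 to 0.0619). The transcription factors KLF4 and KLF15 fell by 1.09 ± 0.17 and 1.01 ± 0.16. Of the 24 tested cholesterol and sterol synthesis genes, 0 rose, 0 fell and 24 did not pass. Tested with camera, the list had adjusted p = 3.26e-09 (adjusted p = 0.436 with an estimated correlation), and 12 and 0 passed adjusted over the list alone. At an unadjusted p under 0.05, 17 rose and 0 fell by edgeR, while DESeq2 called 4 and 0 and limma-voom 0 and 0. The isoprenoid enzyme IDI1 stood at 0.57 ± 0.15 (adjusted p = 0.0546) and passed without M4 or R1 (adjusted p 0.0342 to 0.0449). Among the NF-κB and TNF response genes, 0 of 37 rose, 1 fell and 36 did not pass. Adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.481). The member that fell was PTX3. Of the 23 tested contractile genes, 0 rose, 0 fell and 23 did not pass. These counts were 3 and 0 adjusted over the list alone (camera adjusted p = 0.00135, adjusted p = 0.563 with an estimated correlation). At an unadjusted p under 0.05, 6 rose and 0 fell by edgeR, while DESeq2 called 2 and 0 and limma-voom 0 and 0. The tropomyosin TPM4 stood at 0.31 ± 0.086 (adjusted p = 0.0689) and passed without M2, M4 or R1 (adjusted p 0.0391 to 0.0498). Once 1 library was removed, of the sterol synthesis genes 2 rose without M4 or R1. Leaving out 1 library, of the contractile genes 1 to 2 rose without M2, M4 or R1. When 1 library was omitted, of the quiescence genes 3 fell without M1.

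The third comparison, primed stromal medium against serum-free medium after TGF-β, asked the same of stromal cells first stimulated with interferon-γ and tumour necrosis factor α. Among genes with at least 5 CPM in the higher group and no overlap between the groups, CXCL8 (interleukin-8), a chemokine that attracts neutrophils, rose by 6.38 ± 0.88 (adjusted p = 5.25e-05), from 0.141 ± 0.142 to 12.1 ± 19.6 CPM. P2 had 47.1 CPM of CXCL8 and the other primed libraries 1.59 to 5.83, and the untreated fibroblasts had 1.41 ± 0.477 CPM. The chemokine CXCL6 rose by 5.94 ± 0.85 (adjusted p = 7.58e-05), the acute phase gene SAA1 by 5.39 ± 0.65 (adjusted p = 1.10e-05) and C3 by 5.24 ± 0.60 (adjusted p = 6.27e-06), to 95.9 ± 87.7 CPM in P. The chemokines CXCL1 and CCL2, the latter for monocytes, rose by 4.98 ± 0.61 (adjusted p = 1.35e-05) and 4.29 ± 0.31 (adjusted p = 1.48e-08). The collagenase MMP1 rose by 2.60 ± 0.36 (adjusted p = 5.23e-05) and IL6 by 1.86 ± 0.34 (adjusted p = 0.00102), each with no overlap between the 5 libraries of either group (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Within the same limits the largest falls were in the cartilage proteoglycan ACAN (−4.06 ± 0.61), HAPLN3 (−2.96 ± 0.37), MGP (−2.32 ± 0.38), TNXB (−2.20 ± 0.22), the matricellular protein SMOC2 (−1.999 ± 0.35) and RIPOR2 (−1.99 ± 0.26). Without P2, CXCL8, CXCL6, SAA1, C3 and CXCL1 rose by 4.53, 4.33, 4.39, 4.59 and 3.63. CXCL8 rose by 7.07 without M2, and ACAN and MGP stood at −4.75 and −2.99 without P3.

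ACTA2 stood at 618 ± 290.3 CPM in P against 899.6 ± 155 in M, a log2 difference of −0.54 ± 0.23 that did not pass (adjusted p = 0.158) but passed without P1 (adjusted p = 0.0303) and with the replicate block, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ACTA2 was 315 in P4 and 316 in P5, against 726 to 964 in P1 to P3. COL1A1 fell by 0.76 ± 0.20 (adjusted p = 0.0191), a call lost without M1 (adjusted p = 0.0520), and stood at 22074 in P4 and 22738 in P5 against 49033 to 54064 in P1 to P3. COL1A2 (−0.50 ± 0.17, adjusted p = 0.0732) did not pass, but did without P2 or P3 (adjusted p 0.0260 to 0.0485) and with the replicate block, DESeq2, limma-voom, limma-trend or the residual component. TIMP1 rose by 0.73 ± 0.21 (adjusted p = 0.0326), lost without M1, M3, M5, P1, P2 or P3 (adjusted p 0.0616 to 0.105). MKI67 rose by 1.67 ± 0.42 (adjusted p = 0.0146), lost without P4 or P5 (adjusted p 0.0559 to 0.0636). CDKN1A (0.25 ± 0.080, adjusted p = 0.0589) passed without P5 (adjusted p = 0.0351), with the replicate block, DESeq2, limma-voom or the residual component, and without the GC trend, and IDO1 (−3.68 ± 1.78, adjusted p = 0.234; −1.16 without M5, and P1 held all counts in P) did not pass. In all, 1687 genes differed between P and M, 865 higher and 822 lower (739 and 993 with upper-quartile scaling, 1828 and 1485 with the replicate block), 286 and 222 of them by at least 2-fold, and 1081 had no overlap between the groups.

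Of the gene lists, 12 of 29 differed, 8 upward and 4 downward. The NF-κB, interferon-γ and basement membrane lists did so with an estimated correlation as well. Among the NF-κB and TNF response genes, 28 of 37 rose, 0 fell and 9 did not pass. By camera, adjusted p = 6.71e-33 (adjusted p = 0.00777 with an estimated correlation), and 31 rose and 1 fell adjusted over the list alone. After CXCL8 and CXCL6 the largest rise was that of CXCL5, another neutrophil chemokine (5.82 ± 0.79, or 4.41 without P2). Of the 29 tested interferon-γ response genes, 9 rose, 0 fell and 20 did not pass. Camera gave adjusted p = 3.08e-06 (adjusted p = 0.0201 with an estimated correlation), and 11 rose and 1 fell adjusted over the list alone. ICAM1 (2.19 ± 0.15), CFB (1.96 ± 0.30) and GBP5 (1.57 ± 0.38, with 129 counts over M and 422 over P) rose most. Among the MHC class I and immunoproteasome genes, 5 of 18 rose, 0 fell and 13 did not pass. As a list they had camera adjusted p = 9.34e-07 (adjusted p = 0.138 with an estimated correlation), with 8 up and 0 down adjusted over the list alone. HLA-B rose by 1.19 ± 0.12, PSMB9 by 0.92 ± 0.23 and β2-microglobulin, B2M, by 0.70 ± 0.10. The list mean was 4.29 in P4 and 4.43 in P5, 4.56 to 4.69 in P1 to P3 and 4.07 to 4.24 in M. Of the 34 tested type I interferon stimulated genes, 2 rose, 1 fell and 31 did not pass. The list as a whole gave camera adjusted p = 0.566, and the counts adjusted over the list alone were 3 and 2. EPSTI1 rose by 1.27 ± 0.19 and the exonuclease gene ISG20 fell by 1.55 ± 0.25. Among the anti-apoptotic genes, 4 of 14 rose, 0 fell and 10 did not pass. It came to 5 and 0 adjusted over the list alone, with camera adjusted p = 0.000326 (adjusted p = 0.0536 with an estimated correlation). Their mean log2 level was 5.51 in P4 and 5.42 in P5, 4.94 to 5.15 in P1 to P3 and 4.70 to 4.79 in M. BIRC3 (2.30 ± 0.25) and TNFRSF11B (1.79 ± 0.14) led, and BIRC5 rose by 1.74 ± 0.50 (1.14 without P4), lost without M1, M3, M5, P4 or P5 (adjusted p 0.0719 to 0.160). Of the 24 tested NRF2 and oxidative stress genes, 4 rose, 0 fell and 20 did not pass. The numbers adjusted over the list alone were 5 and 0 (camera adjusted p = 0.000713, adjusted p = 0.227 with an estimated correlation). The mitochondrial superoxide dismutase SOD2 rose by 3.58 ± 0.21, from 85.7 ± 4.31 to 1021 ± 477 CPM, and the metallothioneins MT2A and MT1E by 1.63 ± 0.25 and 1.08 ± 0.23. Leaving out 1 library, of the type I interferon genes 1 rose without M1, M2, M5, P2 or P3 and 2 fell without M4 or P3. When 1 library was omitted, of the interferon-γ response genes 1 fell without M3, M4, P3 or P4. Dropping 1 library, of the NRF2 genes 7 rose without M2 and 1 fell without P5.

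Among the fibrillar collagens and matrix glycoproteins, 1 of 33 rose, 12 fell and 20 did not pass. Over the list alone, the adjusted calls were 1 up and 15 down (camera adjusted p = 7.64e-09, adjusted p = 0.192 with an estimated correlation). Their mean log2 level was 9.95 in P4 and 9.90 in P5, against 10.41 to 10.55 in P1 to P3 and 10.58 to 10.67 in M. MFAP4 (−1.18 ± 0.13), COL5A3 (−1.15 ± 0.13) and COL8A2 (−0.84 ± 0.12) fell most. Of the 14 tested basement membrane genes, 0 rose, 8 fell and 6 did not pass. Adjustment over the list alone gave 0 higher and 9 lower (camera adjusted p = 3.63e-07, adjusted p = 0.0201 with an estimated correlation). The type IV collagen chains COL4A1 and COL4A2 fell by 0.64 ± 0.15 and 0.55 ± 0.13. Among the TGF-β target genes, 2 of 25 rose, 5 fell and 18 did not pass. This list had camera adjusted p = 0.105, with 3 and 6 adjusted over it alone. The list passed without M3, P2 or P3 (camera adjusted p 0.0461 to 0.0496), and 0 rose with upper-quartile and 1 with DESeq2-type scaling. COMP (−1.40 ± 0.21) and elastin, ELN (−1.15 ± 0.24), fell. Of the 23 tested contractile genes, 3 rose, 2 fell and 18 did not pass. Tested with camera, the list had adjusted p = 0.352, and 3 and 3 passed adjusted over the list alone. Here P4 stood at 7.58 and P5 at 7.49, P1 to P3 at 7.92 to 8.11 and M at 7.93 to 8.01. The myosin light chain kinase MYLK rose by 0.58 ± 0.15, lost without P2 (adjusted p = 0.0551). Among the matrix-degrading proteases, 6 of 27 rose, 5 fell and 16 did not pass. Adjusted over the list alone, 7 rose and 6 fell (camera adjusted p = 0.736). Cathepsin S, CTSS, rose by 3.19 ± 0.30 and stromelysin-1, MMP3, by 2.84 ± 0.52 (1.77 without P2). When 1 library was omitted, of the basement membrane genes 5 fell without M3 or P5. Dropping 1 library, of the contractile genes 1 rose without M3, M5 or P2 and 0 to 1 fell without M1, M2, M3, M4, M5, P4 or P5. If 1 library was left out, of the fibrillar matrix genes 0 rose without M3, M5 or P2. On omission of 1 library, of the TGF-β target genes 0 to 1 rose without M1, M3, M4, M5, P2 or P5.

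Of the 33 tested hypoxia and glycolysis genes, 20 rose, 0 fell and 13 did not pass. These counts were 29 and 0 adjusted over the list alone (camera adjusted p = 5.47e-17, adjusted p = 0.0536 with an estimated correlation). The list mean was 5.84 in P4 and 5.87 in P5, 6.21 to 6.51 in P1 to P3 and 5.52 to 5.66 in M. BNIP3 (1.56 ± 0.17), ADM (1.24 ± 0.18) and PDK1 (1.17 ± 0.18) rose most. Among the cell cycle genes, 14 of 43 rose, 0 fell and 29 did not pass. By camera, adjusted p = 0.000107 (adjusted p = 0.604 with an estimated correlation), and 22 rose and 0 fell adjusted over the list alone. Mean log2 levels of the list were 2.34 in P4 and 1.94 in P5, against 0.76 to 1.02 in P1 to P3 and 0.67 to 1.17 in M. The phosphatase CDC25C rose by 2.16 ± 0.64 (1.30 without P4), lost without M1, M3, M4, M5, P4 or P5 (adjusted p 0.0558 to 0.231). Of the 28 tested immediate early and heat shock genes, 1 rose, 11 fell and 16 did not pass. Camera gave adjusted p = 0.00105 (adjusted p = 0.297 with an estimated correlation), and 1 rose and 14 fell adjusted over the list alone. EGR3 fell by 2.16 ± 0.31. FOS fell by 1.75 ± 0.51 (2.42 without P3), lost without M3, M5, P1, P2 or P5 (adjusted p 0.0541 to 0.0926). Among the endothelial markers, 0 of 11 rose, 3 fell and 8 did not pass. As a list they had camera adjusted p = 0.0778, with 1 up and 3 down adjusted over the list alone. The list passed without M2 (camera adjusted p = 0.0289). The cadherin CDH5 (−3.40 ± 0.51), ERG (−1.34 ± 0.21) and the angiopoietin receptor TEK (−0.96 ± 0.13) fell. Dropping 1 library, of the cell cycle genes 1 to 22 rose without M1, M3, M5, P1, P4 or P5. If 1 library was left out, of the endothelial genes 1 rose without P1 or P3. On omission of 1 library, of the immediate early genes 0 rose without P4 or P5 and 4 to 7 fell without M3, M5, P1, P2, P4 or P5.

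The fourth comparison set primed against resting medium, so that the stimulation of the stromal cells was the only difference the labels give. Among genes with at least 5 CPM in the higher group and no overlap, CXCL8 was higher by 7.86 ± 1.005 (adjusted p = 5.67e-05), CXCL6 by 6.32 ± 0.88 (adjusted p = 0.000155) and CXCL1 by 5.00 ± 0.61 (adjusted p = 3.77e-05). C3 (4.76 ± 0.59), SAA1 (3.81 ± 0.59) and CCL2 (3.73 ± 0.30, adjusted p = 8.92e-08) followed. Without P2, CXCL8, CXCL6, CXCL1, C3 and SAA1 were higher by 6.01, 4.71, 3.65, 4.11 and 2.81. IL6 was higher by 1.74 ± 0.34 (adjusted p = 0.00361) and MMP1 by 1.56 ± 0.35 (adjusted p = 0.0106). ACTA2 was lower in P, 618 ± 290.3 CPM against 1116 ± 134 in R (−0.85 ± 0.23, adjusted p = 0.0353), with overlapping groups, and this call was lost without R1, R2, R3, R4, P4 or P5 (adjusted p 0.0566 to 0.0900). COL1A1 (−0.24 ± 0.20, adjusted p = 0.636), COL1A2 (−0.27 ± 0.17, adjusted p = 0.487), TIMP1 (−0.14 ± 0.21), IDO1 (−4.39 ± 1.76; −2.70 without R1, and P1 held all counts in P), CDKN1A (0.046 ± 0.080) and MKI67 (0.77 ± 0.41) did not pass (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the largest falls within these limits were ACAN (−3.27 ± 0.59, or −3.96 without P3), HAPLN3 (−1.80 ± 0.35), RIPOR2 (−1.68 ± 0.26), INMT (−1.60 ± 0.36) and the integrin ITGA4 (−1.39 ± 0.25).

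In all, 791 genes differed between P and R, 493 higher and 298 lower, 168 and 60 of them by at least 2-fold. Of these, 552 had no overlap between the groups. The count came to 513 without R2, 502 without R4, 527 without P4 and 492 without P5. With only the 10 libraries compared in the fit, 237 were higher and 72 lower, and with the replicate block 795 and 672. Of the gene lists, 15 of 29 differed, 7 upward and 8 downward, and the NF-κB and interferon-γ lists did so with an estimated correlation. Of the 37 tested NF-κB and TNF response genes, 29 rose, 0 fell and 8 did not pass. The list as a whole gave camera adjusted p = 4.09e-50 (adjusted p = 0.000864 with an estimated correlation), and the counts adjusted over the list alone were 32 and 0. CXCL5 was higher by 5.73 ± 0.81 (4.29 without P2). Among the interferon-γ response genes, 9 of 29 rose, 0 fell and 20 did not pass. It came to 14 and 1 adjusted over the list alone, with camera adjusted p = 2.09e-09 (adjusted p = 0.00345 with an estimated correlation). ICAM1 (2.23 ± 0.15), CFB (1.93 ± 0.30) and the transcription factor IRF1 (1.49 ± 0.19) led. Of the 18 tested MHC class I and immunoproteasome genes, 3 rose, 0 fell and 15 did not pass. The numbers adjusted over the list alone were 8 and 0 (camera adjusted p = 1.24e-06, adjusted p = 0.167 with an estimated correlation). The list mean was 4.16 to 4.27 in R, 4.56 to 4.69 in P1 to P3, 4.29 in P4 and 4.43 in P5. HLA-B was higher by 1.03 ± 0.12. B2M was higher by 0.42 ± 0.10, lost without R1 or R5 (adjusted p 0.0564 to 0.0583), and the peptide transporter TAP1 by 0.35 ± 0.085, lost without R4 (adjusted p = 0.0601). Among the NRF2 and oxidative stress genes, 3 of 24 rose, 0 fell and 21 did not pass. Over the list alone, the adjusted calls were 7 up and 0 down (camera adjusted p = 1.25e-06, adjusted p = 0.142 with an estimated correlation). SOD2 was higher by 2.94 ± 0.21 and ferritin heavy chain, FTH1, by 0.84 ± 0.083.

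Of the 23 tested contractile genes, 1 rose, 3 fell and 19 did not pass. Adjustment over the list alone gave 1 higher and 10 lower (camera adjusted p = 1.57e-05, adjusted p = 0.327 with an estimated correlation). In R the list mean was 8.03 to 8.17 (log2), in P1 to P3 7.92 to 8.11, in P4 7.58 and in P5 7.49. ACTA2 (−0.85 ± 0.23) was lost without R1, R2, R3, R4, P4 or P5 (adjusted p 0.0566 to 0.0900). CNN1 (−0.72 ± 0.17) was lost without P4 (adjusted p = 0.0622). Vinculin, VCL, fell by 0.50 ± 0.10. Among the fibrillar collagens and matrix glycoproteins, 0 of 33 rose, 2 fell and 31 did not pass. This list had camera adjusted p = 0.000106 (adjusted p = 0.553 with an estimated correlation), with 0 and 3 adjusted over it alone. The means were 10.36 to 10.53 in R, 10.41 to 10.55 in P1 to P3, 9.95 in P4 and 9.90 in P5. COL8A1 fell by 0.95 ± 0.16. Of the 24 tested cholesterol and sterol synthesis genes, 0 rose, 1 fell and 23 did not pass. Tested with camera, the list had adjusted p = 3.86e-10 (adjusted p = 0.327 with an estimated correlation), and 0 and 2 passed adjusted over the list alone. Here R stood at 6.37 to 6.65, P1 to P3 at 6.05 to 6.54, P4 at 5.17 and P5 at 5.58. IDI1 fell by 0.57 ± 0.15, lost without R2, R3, R4, R5, P4 or P5 (adjusted p 0.0735 to 0.128). Among the TGF-β target genes, 0 of 25 rose, 0 fell and 25 did not pass. Adjusted over the list alone, 0 rose and 0 fell (camera adjusted p = 0.970). At an unadjusted p under 0.05, 5 rose and 2 fell by edgeR, while DESeq2 called 0 and 0 and limma-voom 0 and 0. TGFB1 itself stood at −0.35 ± 0.11 (adjusted p = 0.0979), passing without P3 (adjusted p = 0.0283) and with the replicate block. On omission of 1 library, of the sterol synthesis genes 0 to 3 fell without R1, R2, R3, R4, R5, P1, P2, P4 or P5. After removal of 1 library, of the contractile genes 0 rose without R1, R2, R3, R4, R5, P4 or P5 and 1 fell without P4. Once 1 library was removed, of the fibrillar matrix genes 1 to 4 fell without R1, R4, P1, P2, P3, P4 or P5. Leaving out 1 library, of the TGF-β target genes 1 rose without P3 and 1 fell without P3.

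Genes that moved back had changed with TGF-β and then in the opposite direction. With resting medium 168 genes did so, while 173 changed further in the same direction. Independent lists of these sizes would give 100.4 and 101.1. Without M1, M3 and M5 the 168 became 91, 95 and 89. With primed medium 635 genes moved back and 565 moved further, where independent lists give 375.4 and 375.1. Both comparisons share the M libraries, which alone sets their fold changes against each other. With M1 and M2 against F and M3 to M5 as control, 78 genes moved back and 114 further with resting medium. With primed medium these were 381 and 405. With M4 and M5 against F and M1 to M3 as control, these were 64 and 67, and 354 and 297. Among changes of at least 2-fold in both comparisons, 28 genes moved back and 32 further with resting medium, and 206 and 115 with primed medium. The covariance of the fold changes was −0.0230 for resting and −0.0567 for primed medium. Simulations in which only F differed gave −0.0456 ± 0.00443 and −0.0474 ± 0.00315 (SD, n = 20), differences of 0.0225 and −0.00925. Those without any change gave −0.0404 and −0.0407, differences of 0.0174 and −0.0160. Fold changes correlated at −0.0418 and −0.0838, and with M split at 0.0577 and 0.0214 for resting and −0.00182 and −0.0309 for primed medium. With both media 105 genes moved back. The part undone had medians of 63.0% (R) and 68.9% (P) and upper quartiles of 106% and 108%. Selecting called reversals with M shared can inflate these, so overshoot of F is not shown.

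**Figure D3:**
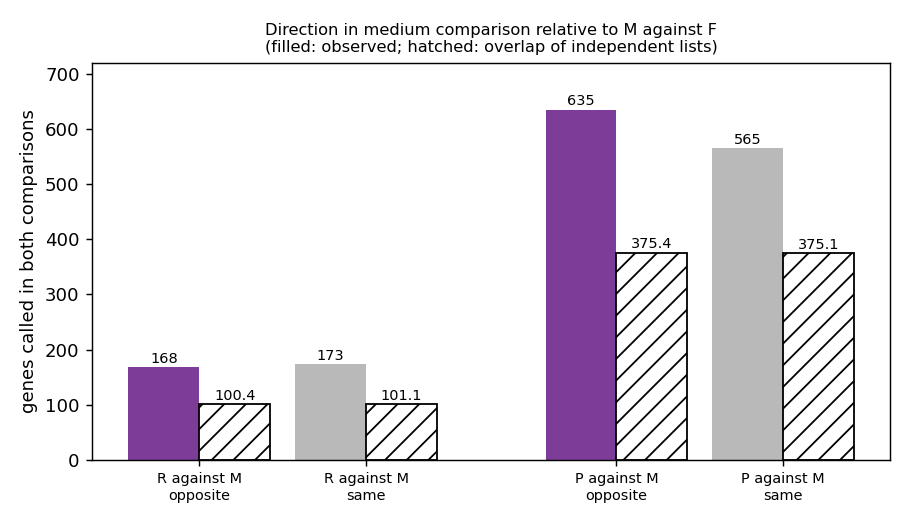
Number of genes changed by TGF-β that changed in the opposite or the same direction with resting (R) or primed (P) medium, as filled bars, beside the overlap that independent lists of these sizes give, as hatched bars. With primed medium 635 genes changed in the opposite and 565 in the same direction, against 375.4 and 375.1.

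The effects of both media on the myofibroblasts were also set side by side. Of the genes changed by both media, 267 changed in the same direction with resting as with primed medium and 2 in opposite directions, where independent lists give 18.1 and 18.3. With separate M libraries as controls for each medium, 57 and 39 genes changed in the same direction and 1 and 0 in opposite directions. The correlation of the fold changes was 0.515, where the shared M libraries alone gave 0.497 in simulation (highest 0.515), and it was 0.180 and 0.253 with separate M libraries. The covariance was 0.113 against 0.0407 in the same simulations, a difference of 0.0723. TNXB fell with resting (−1.99 ± 0.22) and primed medium (−2.20 ± 0.22), as did COMP (−1.30 ± 0.21 and −1.40 ± 0.21), COL5A3 (−1.27 ± 0.13 and −1.15 ± 0.13) and EGR3 (−1.53 ± 0.30 and −2.16 ± 0.31), while TNFRSF11B (1.33 ± 0.14 and 1.79 ± 0.14), BNIP3 (1.01 ± 0.17 and 1.56 ± 0.17) and PDK1 (0.90 ± 0.18 and 1.17 ± 0.18) rose with both.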

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

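The tests of ACTA2 below, of GC content (weights of genes and removal of the trend), of the replicate numbers and of stromal transcripts were chosen after seeing the data. Libraries standing apart from the rest of their group were searched among 304 groups of 5 values; 24 were found, where chance gives 15.2. Values are in CPM.

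P2 stood far above the other primed libraries for inflammatory genes: CXCL8 was 47.1 (others 1.59 to 5.83), CXCL1 220 (10.5 to 44.3), CXCL6 42.2 (1.27 to 6.64), and SAA1 39.3 (2.06 to 12.3). There MMP1 was 656 (118 to 248) and IL7R 16.9 (4.03 to 6.73). P3 stood above the others for MGP, 7.69 (1.36 to 2.61). Among the myofibroblasts, M2 was highest for ACTA2, 1170 (others 800 to 874), M4 for MMP1, 62.3 (40.2 to 46.3), M5 for IDO1, 0.652 (0 to 0.0708), and M3 lowest for TIMP1, 556 (690 to 730). P1 was the only primed library with IDO1, 0.057. In the resting-medium group R1 was lowest for COL10A1, 330 (388 to 405), and for SLC7A14, 0.0343 (0.0894 to 0.106). In the fibroblasts F2 was highest for COL10A1, 0.586 (0.199 to 0.269), F1 for HAPLN1, 0.0795 (0.0145 to 0.0331), and F3 alone had counts of KANK4, 0.0165, and ST6GAL2, 0.00827.

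As means of log2 levels over a list, M2 was high for NRF2 and oxidative stress, 5.71 (others 5.19 to 5.31), and low for quiescent fibroblast factors, 4.14 (4.27 to 4.29). F4 was low for the basement membrane, 7.23 (7.33 to 7.36), and for hypoxia and glycolysis, 5.38 (5.50 to 5.52), and R5 was low for ribosomal proteins, 8.05 (8.16 to 8.19). R5 also had the smallest total of its group, 4.80e+07 counts (1.23e+08 to 1.40e+08). P4 and P5 together stood apart from P1 to P3 in several list means, which the search for single libraries does not find. Among these were ATF4 targets (7.21 and 7.17, others 6.36 to 6.51), sterol synthesis (5.17 and 5.58, others 6.05 to 6.54), collagen processing (6.59 and 6.64, others 7.15 to 7.33), unfolded protein response (6.41 and 6.32, others 6.76 to 6.93), fibrillar matrix (9.95 and 9.90, others 10.41 to 10.55), cell cycle (2.34 and 1.94, others 0.76 to 1.02), contractile (7.58 and 7.49, others 7.92 to 8.11), hypoxia (5.84 and 5.87, others 6.21 to 6.51), anti-apoptotic (5.51 and 5.42, others 4.94 to 5.15), respiratory chain (4.99 and 5.01, others 5.15 to 5.22) and MHC class I (4.29 and 4.43, others 4.56 to 4.69).

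Of the 16 genes with usable counts only in the series-wide table, 7 were called in M against F, 0 in R against M, 2 in P against M and 2 in P against R (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05, 0 of them differed between R and M, and no other tool was run on them. The largest changes, chosen after their values were seen, were rises with TGF-β of the nuclear envelope gene SYNE1 (1.68 ± 0.14), the calcium channel CACNA1C (1.22 ± 0.11) and the collagen receptor DDR1 (1.00 ± 0.13), and of the matrix gene ABI3BP with primed medium (1.34 ± 0.19 against M).

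ACTA2 spread widely among the primed libraries, 964 CPM in P1, 767 in P2, 726 in P3, 315 in P4 and 316 in P5, the highest 3.07 times the lowest. The tables argue against GC content, since the ratio was 3.04 with the GC trend of each library removed. They argue against untreated fibroblasts mixed in: the 6 genes most lowered by TGF-β stood at a median of at most 0.634% of their fibroblast level in a primed library, where the lowest ACTA2 would need 71.1%. A myofibroblast or resting-medium library under a primed label is argued against as well, as the lowest primed NF-κB list mean lay 1.23 (log2) above the highest of the other 10 TGF-β-treated libraries, whose SD was 0.132. A difference in the response of the cells to primed medium, with P4 and P5 apart in the list means above as well, may remain and was not tested.

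The rise of NF-κB genes with primed medium was weighed against carry-over of stromal cells or their RNA. Transcripts abundant in stimulated stromal cells (IDO1, CXCL9, CXCL10, CXCL11, HLA-DRA and CD74) summed to at most 0.0895 CPM in a primed library, against a mean rise of CXCL8 of 11.9 CPM, which was 3.17 without P2 and 1.45 in the lowest primed library. With the GC trend removed 31 members of the list were higher in P than in R, against 29 with the counts as deposited, and without 1 primed library at least 28 were. A response of the cells to factors in the primed medium, residual priming cytokines included, may account for the rise and is a hypothesis; these data cannot separate the cytokines from stromal products.

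Libraries also varied within groups along 1 main direction, which held 21.1% of the variance of the deviations from group means (jackknife SE 3.09). Gene weights on it followed GC content, with Spearman's rho of −0.575 across genes, which are not independent replicates, so a GC-related difference in library preparation is a candidate explanation. Libraries numbered 3 and 4 lay above 0 on it and those numbered 1 and 2 below 0 in each group, and those numbered 5 below 0 except P5 (0.0767). Of 100000 permutations of the numbers within groups, a share of 0.00121 parted them as far, so handling by number is another candidate, although the labels give no batch. Removing the GC trend left 18.4% ± 2.72 and thinning each library to 41502600 counts left 20.6% ± 2.98. No error of these moves was computed, so GC content and depth cannot be told apart from other causes.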

How the results depend on the processing

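The added settings named below (residual component, library numbers, GC trend) and the regroupings were chosen after seeing the data. No call of a named gene or list changed direction under any setting run. The count for M against F (9358) was 5404 with the stricter filter, 5964 with limma-trend (fewer genes tested in both) and 6194 with libraries 3 and 4 only (fewer samples). It was 8803 to 9183 with 1 library left out. For R against M (453) it was 720 with only the groups compared, 969 with DESeq2, 1604 with the residual component, 202 with libraries 1, 2 and 5, 9 with 3 and 4, and 762 without the GC trend. It was 222 to 561 with 1 library left out (232 without M1, 233 without M3, 222 without M5 or R2, 229 without R3, 257 without R4, 279 without R5). For P against M (1687) it was 1004 with only the groups compared, 3863 with the residual component, 230 with libraries 3 and 4 and 1175 to 1806 with 1 library left out. For P against R (791) it was 309 with only the groups compared, 1209 with DESeq2, 1790 with the residual component, 382 with libraries 1, 2 and 5, 99 with 3 and 4 and 1411 without the GC trend. It was 492 to 1044 with 1 library left out (513 without R2, 502 without R4, 527 without P4, 492 without P5). With only the groups compared, 76.7% of the P against R calls were higher, against 62.3%. Except where stated, the cause was not tested.

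With the replicate number as a block, R against M gave 1269 genes, P against M 3313 and P against R 1467, and 436 and 1134 genes moved back; the cause was not tested. The block gave 19 calls of named genes and ended 1, that of CDC25C in P against M. It called MMP1 in M against F, TPM4 and IDI1 in R against M, ACTA2, COL1A2 and CDKN1A in P against M and TGFB1 in P against R, which otherwise did not pass. Of the lists, quiescent fibroblast factors passed in P against M and cell cycle in P against R, and the unfolded protein response no longer did in P against R. Of the 5 pairs of equal number, 3, 3, 2 and 4 correlated above 0.1 in the 4 comparisons in order, and 2, 1, 2 and 3 pairs correlated best with their own number, so not every pair deviated together. The numbers may still mark a shared condition, since the main component of the deviations from group means followed them (0.00121 of permutations as far).

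Of the lists, 2, 0, 3 and 2 passed with an estimated correlation (of 16, 12, 12 and 15). Fry called 6 in R against M and 7 in P against R (3 and 1 of the unchanged lists in simulated data), and with 1 library left out the counts were 15 to 17, 10 to 12, 11 to 15 and 11 to 17. Genes moved back with resting medium (168) were 78 and 64 with split controls, 336 with DESeq2, 286 without the GC trend, 28 with a 2-fold limit and 89 to 196 with 1 library left out (91 without M1, 95 without M3, 89 without M5); with primed medium (635) they were 381 and 354, 206 and 464 to 635. The cause was not tested. Named genes that lost their call with 1 library left out made up 0 of 1090 values for M against F, 125 of 730 for R against M, 101 of 1000 for P against M and 74 of 870 for P against R.

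In 100 splits of 10 libraries, M against F (9358, highest other 834) and P against M (1687, 196) reached the real count 1 time. Chance is excluded there at the 5% limit, as far as libraries are interchangeable. R against M (453, 889) and P against R (791, 4774) reached the real count 2 times. Another split gave more genes there, so chance is not excluded. The splits with 889 (M1, M3, M5, R1 and R5) and 4774 (P1, P2, R1, R2 and R5) point to structure the groups do not explain. Without the GC trend they gave 0 and 1745, and the real groups 762 and 1411. The split with 4774 follows the signs on that main component, which parts numbers 3 and 4 from the others and argues against full interchangeability in each comparison. For lists, 6, 2, 32 and 8 splits reached the real 16, 12, 12 and 15 (highest others 16, 12, 18 and 17). Only R against M met the limit, but another split equalled its count and interchangeability is in doubt, so chance is not excluded. For genes moved back, 2 (168, highest other 540) and 1 (635, highest other 112) did, but a split that calls few genes can move few back, so this says nothing about their direction. Depth limits rare transcripts most in F1 and R5.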

Other observations

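The tests of the lists below were planned; genes at 0 counts were looked at after the results were seen. In the WNT, IGF and growth factor list, 1 of the 42 tested members rose, 3 fell and 38 did not pass with resting medium (3 and 6 adjusted over the list alone, camera adjusted p = 0.285). The EGF-family ligand EREG fell by 3.17 ± 0.56 (3.91 without R1), the platelet-derived growth factor PDGFA by 0.72 ± 0.13 and its receptor PDGFRB by 0.50 ± 0.090 (edgeR's quasi-likelihood test, adjusted p = 0.00307, adjusted p = 0.00333 and adjusted p = 0.00379). With primed medium, 7 of the 42 tested members rose, 10 fell and 25 did not pass (12 and 13 adjusted over the list alone, camera adjusted p = 0.736). With upper-quartile scaling 4 rose. Hepatocyte growth factor, HGF, stood at −1.94 ± 0.33, IGF1 at −1.68 ± 0.42 (−2.49 without P3) and the WNT antagonist SFRP4 at −1.28 ± 0.34, the last lost without M3, M4, P2 or P5 (adjusted p 0.0522 to 0.0607). Primed against resting medium, 8 of the 42 tested members rose, 4 fell and 30 did not pass (9 and 6 adjusted over the list alone, camera adjusted p = 0.766). EREG stood at 4.24 ± 0.54 (4.98 without R1), BMP2 at 0.97 ± 0.16 and IGF2 at 1.27 ± 0.31, lost without R2, R3, R4 or P2 (adjusted p 0.0545 to 0.0768). After removal of 1 library, of the growth factor genes 4 rose without M3 or M5 and 6 fell without M3. Once 1 library was removed, of the growth factor genes 5 rose without R2.

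Other lists differed between primed and resting medium. Of the ATF4 targets, 2 of the 26 tested members rose, 0 fell and 24 did not pass (7 and 0 adjusted over the list alone, camera adjusted p = 0.000286, adjusted p = 0.648 with an estimated correlation). The number that rose was 1 to 6 without R3, R4, P1, P2, P3 or P5. Their mean log2 level was 7.21 in P4 and 7.17 in P5, against 6.36 to 6.51 in P1 to P3 and 6.40 to 6.51 in R. CEBPB rose by 0.77 ± 0.13 and the glycoprotein hormone STC2 by 0.87 ± 0.20, lost without R3, R4 or P5 (adjusted p 0.0503 to 0.0596). Of the hypoxia and glycolysis genes, 2 of the 33 tested members rose, 0 fell and 31 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.00275, adjusted p = 0.648 with an estimated correlation). The list did not pass without P2 or P3 (camera adjusted p 0.0568 to 0.215). With upper-quartile scaling 1 rose. VEGFA rose by 0.68 ± 0.15 and ADM by 0.66 ± 0.17, lost without R2, R3, R4, P2 or P5 (adjusted p 0.0690 to 0.108). Once 1 library was removed, of the hypoxia genes 1 to 4 rose without R2, R3, R4, P2 or P4.

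The interferon-inducible chemokine genes CXCL10 and CXCL11 and the class II gene HLA-DRA had 0 counts in the 20 libraries, which allows at most 0.0723 CPM in the shallowest, and CXCL9 had 10 counts in 1 fibroblast library. IDO1 had counts in 9 of the 20 libraries, 277 in F, 135 in M, 152 in R and 7 in P in sum, and 164 of them in F4. These genes were chosen after their values were seen.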
